A study of Mus musculus with 8 samples.

How the data were processed

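RNA was sequenced from spermatocytes in pachynema and diplonema (PD) and from round spermatids (RS), each sorted by flow cytometry from het and conditional knockout (cKO) mice. Per the labels' protocols, libraries were made with a KAPA RNA Hyper Prep kit. The 4 groups of 2 libraries were taken from the sample titles, and columns were matched to samples by their names. The header of the normalized counts of het RS replicate 1 lacks a letter of the name and was given to the sample left over: 0.24% of genes are above 0 in only 1 of that column and the FPKM column of that library, against at least 7.4% for any other library. Bowtie2, Cufflinks and the mm10 build are named in the submitters' processing notes, without versions or roles. The annotation release, the filters and the handling of strand are not given in the sources used here, so a gene and an overlapping antisense gene cannot be told apart.

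The authors deposited 1 table of 38924 genes with an FPKM value (fragments scaled to transcript length and library depth by the authors) and a normalized count per gene and library, per the file headers. The normalized counts are a signal that the authors had divided by 1 factor per library in the table as deposited, judging by its headers and values: between 59.3% and 63.1% of values under 200 are whole multiples, within 0.011, of the smallest common step of their library. Whole reads could therefore not be recovered, and no test for counts was run. Dividing by that step gave an estimated 31700000 to 48800000 reads per library, which is an estimate and not a stated depth. No counting interval is given for a share, because the deposited values are not whole reads. The authors' group means and SDs in the same table differed from those of the 2 library columns in 0 values, at a tolerance of 0.00001 times 1 plus the value, and were not used further.

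Gene symbols were taken from the table, and 37607 gene identifiers matched GENCODE vM21 (GRCm38), which gave coordinates and chromosomes. FPKM values of 157 symbols with more than 1 row were summed. Genes with an FPKM of at least 1 in at least 2 libraries were kept, which left 18440 genes. Values were tested as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. FPKM depends on the transcript length that the authors' software assigned. A gene whose reads move between short and long transcripts can thus change in FPKM without a like change in reads. Whether that length was assigned per library or per group is not given in the sources used here. If it was set per group, the spread between the libraries of a group leaves its error out.

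The test was limma 3.58.1 in R 4.3.3, with 1 mean per group over all 8 libraries (4 residual degrees of freedom), moderated variances with a mean-variance trend, and Benjamini-Hochberg adjustment over genes, with an adjusted p of 0.05 as the threshold. The comparisons were cKO against het in PD, cKO against het in RS, RS against PD in het, RS against PD in cKO, and the interaction, which is the genotype difference in RS minus that in PD. Errors of log2 fold changes are standard errors of limma, and ± after an FPKM is the SD of 2 libraries.

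Gene lists were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, for both genotype comparisons and the interaction. The same tests were run for RS against PD in het, where 22 of 28 lists passed camera, and 0 with an estimated correlation. For that comparison only counts of members are reported. The lists were chromatin compaction, acrosome, axoneme, tail accessory structures, manchette and head shaping, sperm energy enzymes, haploid transcription and mRNA regulators, postmeiotic sex-chromosome genes, synapsis and recombination, meiotic division, piRNA pathway, sex body and DNA damage response, p53 targets and apoptosis, stress and immediate early genes, spliceosome, mitochondrially encoded genes, ribosomal proteins, replication-dependent histones, markers of Sertoli, Leydig, peritubular and stromal, macrophage and blood, and spermatogonial cells, and all X-linked and all Y-linked genes. Adjustment over lists also took in 1 further fixed list whose results are not used here. Fixed lists share 3 genes. A stage-up and a stage-down list, at least 4-fold higher or lower in het RS than in het PD at the threshold, were chosen on these samples, share the het libraries with the genotype comparisons and are not independent evidence. Unchanged libraries drawn around the het means (100 draws) gave the values that shared controls alone would bring. Genes varied independently in these draws, unlike real ones, so the ranges are narrower than for genes that move together.

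The lists, comparisons, tests, the first 8 variations below and the rule for named genes were fixed before the data were examined. Named genes are Ewsr1; up to 12 genes with the highest and 12 with the lowest log2 fold change per genotype comparison, or 5 and 5 for stage and interaction, among genes past the threshold whose groups did not overlap and whose higher mean was at least 5 FPKM, leaving out predicted gene models and clones; and up to 4 members of each list past the threshold or, if none passed, the 2 with the highest mean. That rule and 6 genes added by hand gave 298 results; the text names part of them, picked after their values were seen. Genes outside that rule are marked where they are named.

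Choices of processing were varied in turn: a pseudocount of 0.1, no filter on low values, rescaling of FPKM by factors from a trimmed mean of M values (TMM, trims of 30% and 5%), the replicate number as a block, fits of only the 4 libraries compared, limma without the trend, the highest row per symbol, and leaving out each library in turn. Normalized counts in place of FPKM, a filter of 10 normalized counts in 2 libraries, and leaving out both libraries labelled cKO that share a replicate number were added after seeing the data. The functions were tested on simulated data with the real means and spreads of all 18440 genes, with 200 genes changed in 1 group. These 200 were drawn from genes with a mean log2(FPKM + 1) of at least 4, so recovery of lower genes was not tested. Of genes changed 4-fold, limma recovered 95% for genotype in PD, 95% for genotype in RS and 80.5% for the interaction; of those changed 2-fold it recovered 0% in each of these comparisons. The simulated genes varied independently, unlike real ones. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.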

Results

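Germ cells were sorted from testes of 8-week-old mice and their RNA was sequenced. The cells were spermatocytes in pachynema and diplonema, the long middle part of meiotic prophase (PD), and round spermatids, the haploid cells that follow meiosis (RS). All mice carried a Cre recombinase driven by the Hspa2 promoter, which is active in spermatocytes, and 1 loxP-flanked copy of Ewsr1. The other copy was intact in het mice and is marked as minus in conditional knockout (cKO) mice. Ewsr1 encodes an RNA- and DNA-binding protein. Each of the 4 groups held 2 libraries with an estimated 31700000 to 48800000 reads. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these libraries. The series title asks about transcription after meiosis and the shaping of sperm.

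Ewsr1 (chromosome 11, 5069689 to 5099266, minus strand, GRCm38) was measured first, since it checks the labels. In PD it stood at 277 and 299 FPKM in the het libraries and at 143 and 290 FPKM in replicates 1 and 2 labelled cKO. In RS the het libraries had 270 and 254 FPKM, and those labelled cKO had 113 and 263 FPKM. Replicate 1 labelled cKO was thus below both het libraries in each cell type, while replicate 2 was at the het level. The log2 fold change was -0.50 ± 0.44 in PD (limma, Benjamini-Hochberg adjusted p = 0.658) and -0.60 ± 0.44 in RS (adjusted p = 0.475, n = 2 libraries per group). It was 0.01 in PD without replicate 1 labelled cKO and 0.01 in RS without replicate 1 labelled cKO; without replicate 2 it was -1 and -1.21. Because the label of replicate 2 is not borne out by this gene, libraries are called labelled cKO throughout, and each direction below holds for the labels. The deleted exons are not given in the sources used here, and reads outside them can remain.

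**Figure D1:**
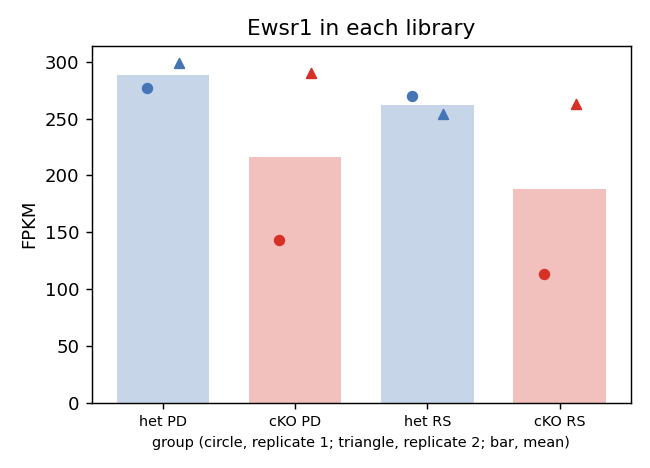
Ewsr1 in FPKM (vertical axis) in each library, by group; bars are means of 2 libraries, circles replicate 1 and triangles replicate 2. Replicate 1 labelled cKO lies at 143 FPKM in PD and 113 FPKM in RS, and replicate 2 at 290 and 263 FPKM, beside the het libraries.

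The first comparison asked how round spermatids differ from spermatocytes in het mice. Genes of sperm chromatin and tail rose from PD to RS. Tnp1 and Tnp2, the transition proteins that replace histones, rose from 2864 ± 152 to 17203 ± 2886 FPKM and from 3010 ± 269 to 15049 ± 2505 FPKM (log2 2.58 ± 0.75, adjusted p = 0.0383, and 2.31 ± 0.58, adjusted p = 0.024; limma, Benjamini-Hochberg, n = 2 libraries per group). Akap4, a scaffold of the fibrous sheath of the tail, rose by 1.65 ± 0.37, Spata19 of the sperm mitochondria by 1.81 ± 0.31 and Hils1, a spermatid linker histone, by 1.77 ± 0.30. Cypt1 and Cypt3, X-linked genes of spermatids, rose by 1.71 ± 0.17 and 1.69 ± 0.16. In the other direction fell Piwil1, the piRNA-binding protein of pachytene cells (-2.09 ± 0.20), its pathway members Mov10l1 (-1.97 ± 0.24) and Tdrd1 (-1.73 ± 0.19), and the meiotic regulators Fbxo43 (-1.59 ± 0.22) and Aurkb (-1.34 ± 0.30). Leaving out any 1 het library ended the calls of Tnp1 (adjusted p 0.114 to 0.165), Tnp2 (0.0836 to 0.13), Akap4 (0.0661 to 0.0975) and Aurkb (0.0539 to 0.101). Without het PD replicate 1, Hils1 (0.0505) and Spata19 (0.052) did not pass, and with no filter on low values Tnp1 (0.0928) and Tnp2 (0.0686) did not.

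Of 16 tail accessory genes 11 rose and 0 fell, with 14 and 0 adjusted over the list alone. Counts of risen and fallen genes were 6 and 1 of 12 for chromatin compaction (8 and 1 adjusted over the list alone), 8 and 0 of 18 for manchette and head shaping, which shapes the nucleus (9 and 0), 5 and 1 of 29 for the acrosome (4 and 1), 5 and 1 of 20 for sperm energy enzymes (5 and 1) and 6 and 0 of 16 for postmeiotic sex-chromosome genes (8 and 0). Spem1, needed to shed sperm cytoplasm, rose by 1.74 ± 0.54, the testis kinase Tssk2 by 1.35 ± 0.25, the glycolytic enzymes Gapdhs and Pgk2 by 1.39 ± 0.35 and 1.14 ± 0.30, Oaz3 of the tail accessory list by 1.63 ± 0.39, and the acrosome and head skeleton genes Ccin and Cylc1 by 1.29 ± 0.19 and 1.26 ± 0.16. Among meiotic lists, 0 rose and 8 fell of 20 piRNA pathway genes, 0 and 6 of 18 sex body and DNA damage response genes (H2afx -1.47 ± 0.25, Mdc1 -0.97 ± 0.17), 2 and 5 of 30 synapsis and recombination genes and 0 and 7 of 22 meiotic division genes. Adjusted over the list alone these were 1 and 9, 0 and 7, 2 and 5, and 0 and 7. The axoneme list had 1 risen and 1 fallen gene of 21, haploid regulators 2 and 2 of 19, ribosomal proteins 0 and 9 of 73 (Rps4x -3.61 ± 0.32 and Rpl10 -2.95 ± 0.27, both X-linked), and the spliceosome 1 and 12 of 29 (Snrpb -2.05 ± 0.17); adjusted over the list alone, 1 and 1, 2 and 2, 0 and 9, and 1 and 13. Leaving out any 1 het library ended the calls of Oaz3 (adjusted p 0.0755 to 0.111), Spem1 (0.126 to 0.202), Gapdhs (0.0778 to 0.131) and Pgk2 (0.121 to 0.129), and no filter on low values ended those of Spem1 (0.0968), Gapdhs (0.0536) and Pgk2 (0.0575). Spem1 was also lost with a pseudocount of 0.1 (0.0513) and in limma without the trend (0.0505). Leaving out certain het libraries ended those of Tssk2 (0.0679 without PD replicate 1, 0.0515 and 0.0631 without RS replicates 1 and 2), H2afx (0.0556 without PD replicate 1, 0.052 without RS replicate 1) and Mdc1 (0.0652 and 0.0531 without RS replicates 1 and 2).

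Markers of other testis cells and stress genes also fell from PD to RS. Dcn of stromal cells fell (-5.70 ± 0.34), as did Insl3 of Leydig cells (-3.41 ± 0.43), Vim of Sertoli and other somatic cells (-3.71 ± 0.30) and Stra8 of cells before meiosis (-2.49 ± 0.42). All 5 peritubular and stromal genes, 7 of 8 Leydig, 9 of 12 Sertoli, 2 of 6 macrophage and blood and 10 of 14 spermatogonial markers fell (5, 8, 9, 2 and 11 adjusted over the list alone). The immediate early genes Fos, Fosb and Egr1, switched on within minutes of handling or stress, fell (-6.54 ± 0.36, -5.57 ± 0.35 and -5.14 ± 0.38), with 14 of 16 stress genes. All 12 mitochondrially encoded genes (mt-Cytb -4.33 ± 0.62), 48 of 57 replication-dependent histones (Hist1h4m -5.00 ± 0.35) and 5 of 10 p53 targets fell as well (12, 49 and 7 adjusted over the list alone, where 1 histone gene rose). By the naming rule the other genes with the largest rises were Rbm31y (4.09 ± 0.16), Styx (3.48 ± 0.26), Prss58 (2.61 ± 0.31) and Defb33 (2.58 ± 0.81, adjusted p 0.135 to 0.176 without any 1 het library), and the other largest falls AY036118 (-8.48 ± 0.26) and the actin-severing gene Gsn (-6.01 ± 0.31). Defb33 was also lost with a pseudocount of 0.1 (limma adjusted p = 0.0555), no filter (0.0993) and limma without the trend (0.0505). The predicted Y-linked model Gm21379 went opposite to Rbm31y, with 272 and 301 normalized counts in het PD and 0 in both het RS libraries. Reads assigned to a different Y-linked copy thus cannot be ruled out for the rise of Rbm31y.

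In all, 1200 genes rose and 4143 fell, so 22.5% of calls were rises. The all-gene median was -0.13 on the log2 scale as deposited and 0.009 after TMM rescaling, which gave 2408 rises and 3458 falls (41.1% rises). Leaving out 1 library, rises ranged from 175 (without het RS replicate 2) to 2141 (without PD replicate 2 labelled cKO) and falls from 1413 (without het RS replicate 1) to 4740 (without PD replicate 1 labelled cKO).

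The second comparison set spermatocyte libraries labelled cKO against het. Few genes passed, 6 higher and 2 lower (limma, Benjamini-Hochberg), with 1500 genes at an unadjusted p under 0.05. Rbm31y, a Y-linked gene of the Rbm31 family, was at 0 in both het PD libraries and at 6.78 and 6.61 FPKM in those labelled cKO (2.94 ± 0.16, adjusted p = 0.00125), against 16.9 and 15.1 FPKM in het RS. The predicted Y-linked model Gm21379 went the other way, with 272 and 301 normalized counts in het PD against 0.11 and 0 in the libraries labelled cKO, where Rbm31y had at most 0.06 against 579 and 524, so reads assigned to a different Y-linked copy cannot be ruled out for either. Cbs, which makes cystathionine from homocysteine, had 0.52 ± 0.481 and 13.6 ± 4.96 FPKM (3.25 ± 0.30, adjusted p = 0.0246), but 30.5 and 17.8 normalized counts in het against 33.8 and 28.3 in the libraries labelled cKO. Its call was lost without any 1 library other than PD replicate 1 labelled cKO (adjusted p for Cbs 0.0544 to 0.166), with no filter (0.0604), a pseudocount of 0.1 (0.135) or normalized counts (0.729). The other 6, Gm21379 among them, were predicted models, and 3 of the 8 had fewer than 10 estimated reads.

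By list, genes of the acrosome, tail and energy supply lay lower and Sertoli and macrophage markers higher in PD libraries labelled cKO, with 1 member, of the stage-down list, past the test over all genes, in the lower direction. Of 20 sperm energy enzymes 19 had negative fold changes (median -0.373, camera adjusted p = 0.00362), among them Ldhc at -0.35 ± 0.33 and Gapdhs at -0.37 ± 0.35. Likewise 26 of 29 acrosome genes were negative (adjusted p = 0.00605; Spink2 -0.40 ± 0.36, Acrbp -0.22 ± 0.16), 15 of 16 tail accessory genes (0.0262; Odf2 -0.24 ± 0.24, Ropn1l -0.57 ± 0.27), 15 of 19 haploid regulators (0.0184; Ybx2 -0.33 ± 0.19), 16 of 22 meiotic division genes (0.0262; Hspa2 -0.38 ± 0.22) and 62 of 73 ribosomal protein genes (0.0186). Positive were all 12 Sertoli markers (0.00362; Clu 0.50 ± 0.36, Vim 0.15 ± 0.30), all 6 macrophage and blood markers (0.00362; Cd74 0.87 ± 0.53, Hba-a1 0.56 ± 0.28), 518 of 801 X-linked genes (0.00153) and 440 of 575 stage-down genes (3.12e-06). Adjusted over the list alone, 0 members passed in these fixed lists, and 6 rose and 2 fell in the stage-down list, which was chosen on these samples. That list lay 0.255 above all genes, where shared het libraries alone gave -0.067 (range -0.103 to -0.036, genes drawn independently). None of the 10 calls held with an estimated correlation (adjusted p = 0.843 with an estimated correlation for each) or with fry (adjusted p = 0.768 with fry for each).

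These list calls rested on 1 library. Without PD replicate 1 labelled cKO none of the 10 lists passed and 3 others did, and the acrosome, tail accessory and stage-down lists changed direction (adjusted p = 0.901, 0.957 and 0.156). The other 7 had adjusted p = 0.901 (energy enzymes), 0.156 (haploid regulators), 0.743 (meiotic division), 0.66 (ribosomal proteins), 0.818 (Sertoli), 0.156 (macrophage and blood) and 0.209 (X-linked). That library also held 20.4% of its normalized counts in mitochondrial genes, against 8.02% and 10.9% in het PD and 8.41% in replicate 2 labelled cKO. Mitochondrially encoded genes had a median of 0.477 (adjusted p = 0.0516; mt-Co1 0.52 ± 0.58, mt-Co2 0.26 ± 0.53). Chromatin compaction (adjusted p = 0.727; Prm1 -0.79 ± 0.70, Tnp1 -0.79 ± 0.75) and manchette genes (0.0559) did not pass, and the remaining lists reported here had adjusted p up to 0.703. Postmeiotic sex-chromosome genes had 11 of 16 positive (0.057). The stage-up list, chosen on these samples, had 32 positive and 38 negative (0.245) and lay 0.03 above all genes, where shared het libraries alone gave 0.218 (range 0.077 to 0.302). Leydig markers (0.217) and peritubular and stromal markers (0.703, 3 of 5 negative) did not pass. Leaving out PD replicate 2 labelled cKO gave 18 lists, and without het PD replicate 2 there were 6, with acrosome, tail, haploid regulator, Sertoli, macrophage and stage-down lists lost (0.0812, 0.193, 0.124, 0.124, 0.156 and 0.151). Without het PD replicate 1, meiotic division (0.0802) and ribosomal proteins (0.654) were lost, and meiotic division also without RS replicate 1 or 2 labelled cKO (0.0528 and 0.0523). Counts of lower genes ranged from 1 (without het PD replicate 1) to 10 (without PD replicate 2 labelled cKO).

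**Figure D2:**
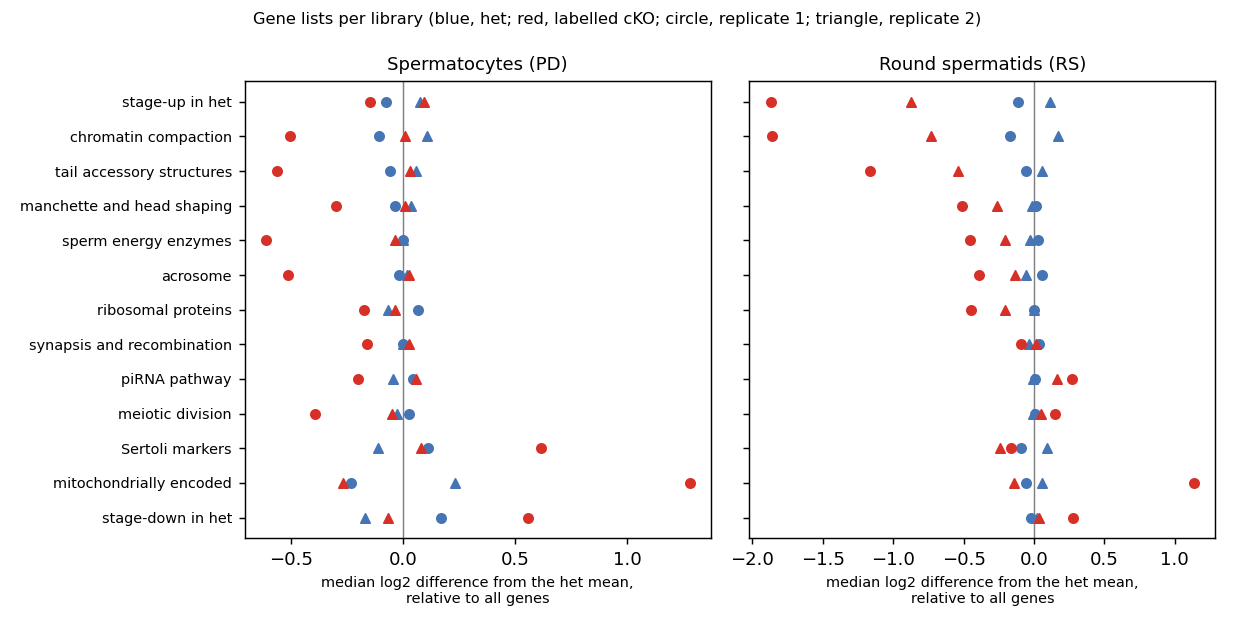
Median log2 difference from the het mean of the same cell type, relative to all genes (horizontal axis), for 13 gene lists in each spermatocyte (left) and round spermatid (right) library; the axes differ in range. In RS the chromatin compaction list lies at -1.86 and -0.73 in replicates 1 and 2 labelled cKO, and in PD at -0.50 and 0.01.

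The third comparison set round spermatid libraries labelled cKO against het. Of 16 tail accessory genes 15, and of 12 chromatin compaction genes 9, were lower in both libraries labelled cKO than in both het libraries, where chance gives 16.7% each way; for the acrosome these were 9 of 29, with 8 higher in both. Of all genes tested 17% were lower and 46.3% higher in both, against 31% and 27.6% of acrosome genes. The difference in shares was not tested. Prm1, the protamine that packs sperm DNA, had 19835 and 26861 FPKM in het against 2657 and 11578 FPKM in replicates 1 and 2 labelled cKO (-2.06 ± 0.70, adjusted p = 0.169; limma, Benjamini-Hochberg). Tnp1 went from 15162 and 19244 to 2218 and 8895 FPKM (-1.94 ± 0.75, adjusted p = 0.194). Akap4 had a log2 fold change of -1.16 ± 0.37 (adjusted p = 0.157) and Gapdhs, the sperm form of the glycolytic dehydrogenase, of -1.14 ± 0.35 (adjusted p = 0.15). None of these genes passed the test alone. Prm2 (-1.82 ± 0.57), Tnp2 (-1.88 ± 0.58), Spem1 (-1.70 ± 0.54) and the tail gene Tppp2 (-1.80 ± 0.63) were chosen after their values were seen and had adjusted p between 0.151 and 0.173.

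**Figure D3:**
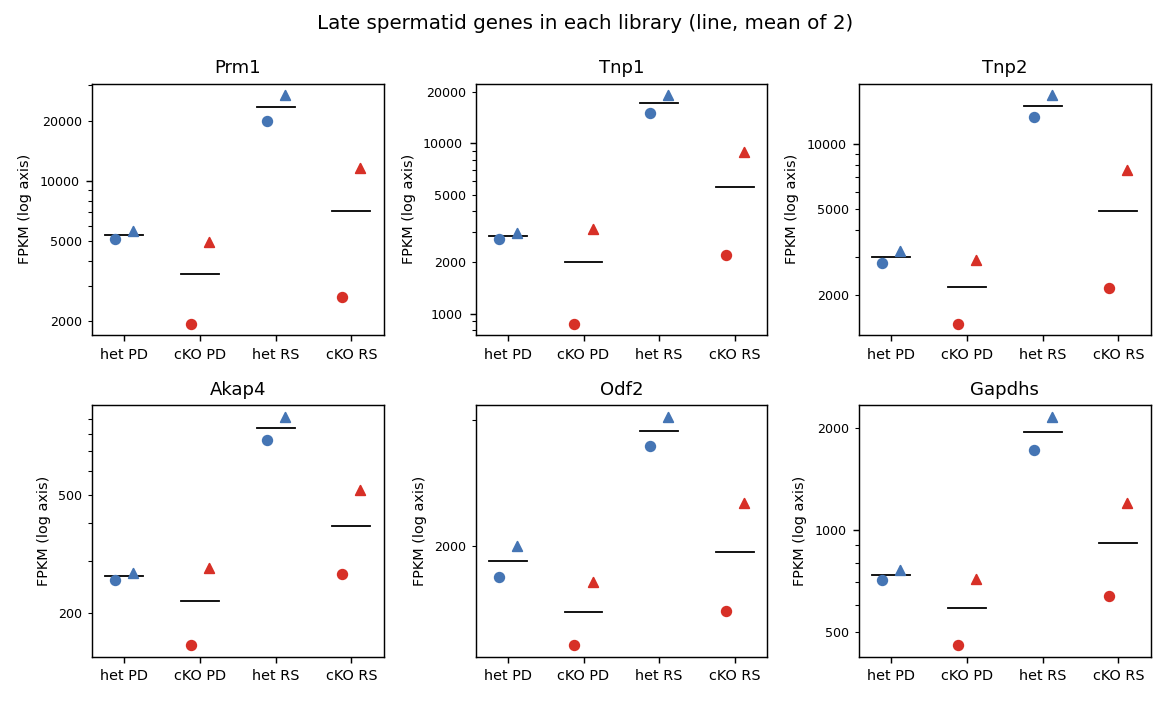
FPKM on log axes for 6 genes of late spermatids in each library, by group; lines are means of 2 libraries, circles replicate 1 and triangles replicate 2. In RS each gene is lower in both libraries labelled cKO than in both het libraries, as for Prm1 at 2657 and 11578 against 19835 and 26861 FPKM.

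As groups, genes of the tail, sperm chromatin, manchette, energy supply and acrosome lay below the rest of the transcriptome, while the axoneme, haploid regulator and postmeiotic sex-chromosome lists did not pass. The all-gene median was 0.143 as deposited and 0.01 after TMM rescaling, so medians are given relative to it. All 16 tail accessory genes were negative (median -0.854 relative to all genes, camera adjusted p = 9.08e-10; Odf2 -0.58 ± 0.24, Ropn1l -0.28 ± 0.27). Chromatin compaction had 11 of 12 negative (-1.289 relative to all genes, adjusted p = 2.22e-06), manchette and head shaping 14 of 18 (-0.374, 0.000116; Hook1 -0.47 ± 0.20, Meig1 -0.27 ± 0.30), sperm energy enzymes 14 of 20 (-0.332, 0.00191; Ldhc -0.13 ± 0.33) and the acrosome 18 of 29 (-0.247, 0.00454; Spink2 -0.01 ± 0.36). Acrbp of the acrosome stood at 0.10 ± 0.16, and at -0.10 after TMM rescaling. Ribosomal protein genes were also lower (57 of 73 negative, -0.332, adjusted p = 2.51e-06; Rpl18 -0.10 ± 0.37, Rps29 -0.24 ± 0.32), as were Y-linked genes (-0.243, adjusted p = 0.0471), whose mean of 0.009 and fry test differ in sign from the median of -0.10. Adjusted over the list alone, 1 chromatin compaction gene rose and 8 fell, 15 Y-linked genes rose and 2 fell, and 0 passed in the tail, manchette, energy, acrosome and ribosomal lists. Over all genes, 0 members of these lists passed. Relative to all genes, these lists lay lower in replicate 1 labelled cKO than in replicate 2. The tail list lay at -1.164 and -0.539, the manchette list at -0.509 and -0.262 and energy enzymes at -0.453 and -0.207. Acrosome genes lay at -0.388 and -0.138, and ribosomal proteins at -0.448 and -0.207. With an estimated correlation none held (adjusted p = 0.922 with an estimated correlation for each). None passed with fry either (adjusted p of 0.298 for chromatin compaction to 0.808 for Y-linked genes).

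In the same libraries 3 fixed lists passed as higher, while synapsis and recombination (camera adjusted p = 0.905) and meiotic division (0.206) did not pass. The piRNA pathway had 17 of 20 positive (0.219 relative to all genes, camera adjusted p = 0.0346), sex body and DNA damage response 17 of 18 (0.188, 0.0238; Dot1l 0.26 ± 0.15) and the spliceosome 27 of 29 (0.074, 0.0439; Hnrnpk 0.30 ± 0.18). All were lost with an estimated correlation (adjusted p = 0.922 with an estimated correlation). With fry they did not pass either (adjusted p = 0.298, 0.214 and 0.214). By library, sex body genes lay at 0.275 and 0.097 relative to all genes in replicates 1 and 2 labelled cKO. The piRNA genes lay at 0.267 and 0.164, and the spliceosome at 0.1 and 0.118. TMM rescaling ended the piRNA, spliceosome and Y-linked calls. Normalized counts ended them as well (0.0918, 0.151 and 0.0554). The spliceosome call was lost in 12 of 20 alternatives, among them a pseudocount of 0.1 (0.0525), the replicate number as a block (0.0591) and limma without the trend (0.0545). All 3 were also lost on leaving out RS replicate 2 labelled cKO (0.126, 0.13 and 0.232); without het RS replicate 1 the piRNA (0.0505) and Y-linked (0.479) lists were lost, and the spliceosome without het RS replicate 2 (0.161) or het PD replicate 1 or 2 (0.0559 and 0.0556). Adjusted over the list alone, 1 piRNA gene passed. Mov10l1, the piRNA helicase, chosen after its values were seen, had 4.72 and 6.17 FPKM in het against 21.2 and 25 FPKM (1.91 ± 0.24, adjusted p = 0.0964), but 900 and 1002 against 1584 and 1230 normalized counts. Sun2 of the nuclear envelope, chosen the same way, had 2.47 ± 0.66 (adjusted p = 0.147).

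The stage-up list, 75 genes chosen on the het libraries and so not independent evidence, had 69 negative genes (-1.46 relative to all genes, camera adjusted p = 7.66e-34). It did not pass in camera with an estimated correlation (adjusted p = 0.922) or in fry (adjusted p = 0.214). Shared het libraries alone gave -0.215 on average (range -0.306 to -0.108 over 100 draws). Of these genes 65 (86.7%) were lower in both libraries labelled cKO than in both het libraries, where shared het libraries alone gave 29.5% (range 21.2% to 40.6%). Both ranges come from genes drawn independently. Real stage-up genes move together (estimated correlation 0.381), so the ranges are too narrow to measure how unusual the observed values are. Over all genes 2 fell, and adjusted over the list alone 1 rose and 53 fell. The 575 stage-down genes lay 0.167 above all genes (adjusted p = 0.00862, 0.922 with an estimated correlation), where shared libraries gave 0.068, and without RS replicate 1 labelled cKO that call was lost (0.394). Adjusted over the list alone, 2 of them rose.

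**Figure D4:**
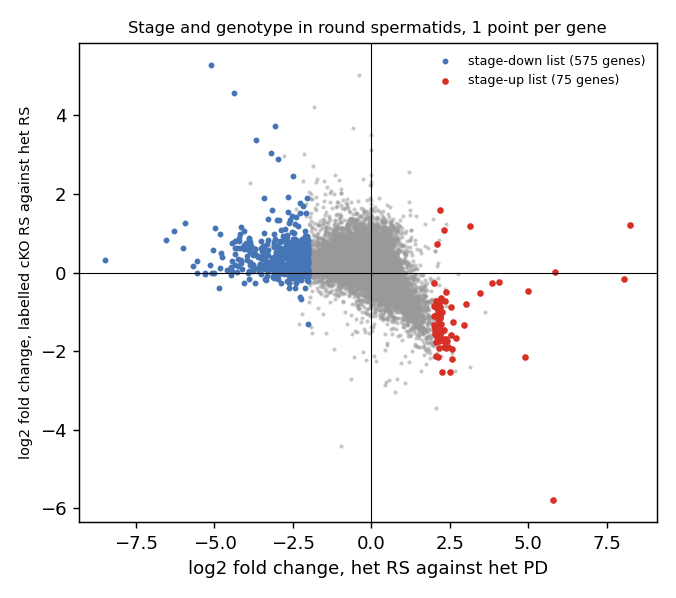
For each of 18440 genes, the log2 fold change of het RS against het PD (horizontal axis) and of RS labelled cKO against het RS (vertical axis); red and blue points are the stage-up and stage-down lists. The axes share the het RS libraries, which alone gives a correlation of -0.163 where -0.436 was observed across genes.

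Other lists in RS did not pass. Camera adjusted p was 0.852 for the axoneme, 0.0785 for haploid regulators, 0.204 for postmeiotic sex-chromosome genes, 0.905 for synapsis and recombination, 0.206 for meiotic division, 0.244 for p53 targets, 0.758 for stress genes, 0.287 for mitochondrially encoded genes (mt-Co1 0.77 ± 0.58; 1.78% of normalized counts in RS replicate 1 labelled cKO, 0.71% to 0.77% in the other RS libraries), 0.758 for replication-dependent histones and 0.41 for X-linked genes. For other cell types it was 0.206 for Sertoli, 0.154 for Leydig (Insl3 1.02 ± 0.43, Fabp3 0.92 ± 0.32), 0.622 for peritubular and stromal, 0.978 for macrophage and blood and 0.94 for spermatogonial markers. Still, 7 of 8 Leydig and 5 of 5 peritubular and stromal markers were higher in both libraries labelled cKO than in both het libraries (46.3% of all genes were), with Leydig markers at a median of 0.391 and peritubular and stromal markers of 0.033 relative to all genes. The median, mean and camera direction differed in sign for the axoneme (median 0.074, camera down) and spermatogonial markers (0.071, down), since camera compares with all genes, and for postmeiotic sex-chromosome genes (median -0.013, mean 0.004).

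Single genes past the test in RS numbered 4 higher and 2 lower (limma, Benjamini-Hochberg), with 4015 at an unadjusted p under 0.05, of which 3079 were higher. E2f3, a cell cycle transcription factor, had 0 and 0.01 FPKM in het against 23.5 and 43.3 FPKM in the libraries labelled cKO (5.04 ± 0.30, adjusted p = 0.00341). Its normalized counts were at most 1.35 in het against 17.1 and 7.36, and it did not pass on that scale (2.45), nor in a fit of the 4 RS libraries (adjusted p = 0.159). The other 5 called genes were predicted models, and 5 of the 6 had fewer than 10 estimated reads. With normalized counts 0 genes passed, at 4518 with an unadjusted p under 0.05. Without RS replicate 2 labelled cKO, with replicate 1 assumed to vary like the other groups, 1271 genes were higher and 490 lower. Leaving out both libraries labelled cKO replicate 2, chosen after seeing Ewsr1, gave 3091 higher and 1636 lower, and leaving out both replicates 1 gave 8 and 5. Without het RS replicate 2 there were 2 higher, and without het RS replicate 1 there was 1 lower.

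The fourth comparison followed the same stages in libraries labelled cKO. The largest falls by the naming rule were Fos at -6.09 ± 0.36, Fosb at -5.48 ± 0.35, Dcn at -5.75 ± 0.34, Gsn at -5.60 ± 0.31 and AY036118 at -8.97 ± 0.26 (limma, Benjamini-Hochberg adjusted p = 0.000435 for Fos). The largest rises by the naming rule were E2f3 (4.56 ± 0.30), KCNQ1OT1_5 (4.31 ± 1.35), the copper chaperone Cox17 (3.32 ± 0.90), Styx (3.27 ± 0.26) and the ciliary gene Rpgrip1 (2.78 ± 0.61). The calls of KCNQ1OT1_5 (adjusted p 0.0719 to 0.142) and Cox17 (0.0529 to 0.12) were lost without any 1 library other than PD replicate 2 labelled cKO, and without PD replicate 1 labelled cKO their fold changes were 1.97 and 1.77. KCNQ1OT1_5 rests on an estimated 1 read in PD and 7 in RS labelled cKO. The call of Rpgrip1 was lost without PD replicate 1 (0.0948), RS replicate 1 (0.0689) or RS replicate 2 (0.0729) labelled cKO. With normalized counts E2f3 passed as lower in RS instead (-2.67, adjusted p = 0.0113), Cox17 had 0.51 and did not pass (adjusted p = 0.0885), and KCNQ1OT1_5 and Rpgrip1 had 2.64 and 0.42, so the sizes of these 4 genes, and the direction of E2f3, hold for FPKM alone. Tnp2, chosen after its values were seen, had 0.97 ± 0.58 (adjusted p = 0.227), against 2.31 in het. In all, 1949 genes rose and 3425 fell, or 390 rises without PD replicate 1 labelled cKO and 4751 without PD replicate 2 labelled cKO. Falls numbered 2011 without RS replicate 2 labelled cKO. Rises were also fewer without either het PD library (719 and 722), either het RS library (586 and 588), RS replicate 1 (427) or RS replicate 2 labelled cKO (997).

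The interaction asked whether the genotype difference is not alike in both cell types. Of 10 lists past the test 7 were lower, among them genes of sperm chromatin and tail: chromatin compaction had a median of -1.01 (camera adjusted p = 1.66e-05; Prm1 -1.26 ± 0.99, adjusted p = 0.644 for Prm1), tail accessory structures -0.438 (0.000148) and the stage-up list -1.16 (1.67e-38). The stage-up list shares the het libraries with this test: it lay at -1.355 relative to all genes, where shared het libraries alone gave -0.438 (range -0.572 to -0.273), and its p takes no account of that. Acrosome genes (median 0.204, adjusted p = 0.708), energy enzymes (0.197, 0.674) and manchette genes (0.1, 0.0563) did not pass, where the all-gene median was 0.195. Meiotic division lay at 0.527 (0.00439; Hspa2 0.52 ± 0.31), the piRNA pathway at 0.371 (0.00514; Mov10l1 2.15 ± 0.34, chosen after its values were seen) and the spliceosome at 0.395 (0.0233). Sertoli markers had -0.375 (0.000394), macrophage and blood markers -0.425 (0.0159), ribosomal proteins -0.003 (0.0426) and postmeiotic sex-chromosome genes 0.022 (0.0119); the means of the last 2 lists, 0.027 and -0.154, differ in sign from their medians. Over all genes 1 stage-up gene and 0 members of the other lists passed; adjusted over the list alone, 1 piRNA gene rose, and 1 postmeiotic sex-chromosome gene and 5 stage-up genes fell. None held with an estimated correlation (adjusted p = 0.885 for stage-up and 0.926 for the others, each with an estimated correlation). With fry none passed either (adjusted p of 0.498 for stage-up to 0.936 for ribosomal proteins). Leaving out 1 library labelled cKO ended list calls of tail (0.0928 without PD replicate 2, 0.0681 without RS replicate 1), Sertoli (0.135), piRNA (0.0539) and macrophage genes (0.188, all without PD replicate 1), and postmeiotic sex-chromosome (0.257), spliceosome (0.0541) and macrophage genes (0.128, all without RS replicate 2). Without 1 het library the macrophage (0.336, PD replicate 2), postmeiotic (0.0752, RS replicate 1) and spliceosome lists (0.0642 and 0.0697, PD replicate 1 and RS replicate 2) were lost, and the ribosomal list was lost without any of 5 libraries (0.0578 to 0.777) and with the replicate number as a block (0.0653). TMM rescaling ended the spliceosome (0.12) and macrophage calls (0.0524). Single genes past the test numbered 3 higher and 3 lower (limma, Benjamini-Hochberg), with 1710 at an unadjusted p under 0.05: E2f3 at 4.96 ± 0.42 (adjusted p = 0.0177), Rbm31y at -3.17 ± 0.22 (adjusted p = 0.00874) and 4 predicted models. Leaving out any 1 het library ended the calls of E2f3 (0.057 to 0.129) and Rbm31y (0.057 to 0.0778), and that of E2f3 was also lost without PD replicate 2 labelled cKO (0.0648) and with normalized counts (2.33, adjusted p = 0.544). Without het PD replicate 2 there were 0 in either direction, at 1201 with an unadjusted p under 0.05. Without PD replicate 2 labelled cKO there were 8 higher, without PD replicate 1 labelled cKO 8 lower, and without het RS replicate 2 there were 0 higher and 1 lower. For Rbm31y, reads assigned to a different Y-linked copy in het PD cannot be ruled out here either.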

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

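The interaction test flagged results whose genotype difference is not alike in both cell types. Single genes were E2f3 (log2 4.96), Gm12736 (3.13), Gm14255 (2.49), 2900097C17Rik (-3.81), Gm20538 (-3.8) and Rbm31y (-3.17) in limma with Benjamini-Hochberg adjustment. For Rbm31y, reads assigned to a different Y-linked copy in het PD cannot be ruled out. Lists were chromatin compaction (median -1.01), tail accessory structures (-0.438), postmeiotic sex-chromosome genes (0.022, tested as lower), meiotic division (0.527), piRNA pathway (0.371), spliceosome (0.395), ribosomal proteins (-0.003, tested as lower), Sertoli markers (-0.375), macrophage and blood markers (-0.425) and the stage-up list (-1.16), which shares the het libraries with the test. None of the lists passed with an estimated correlation or with fry. No group had the 4 samples that an outlier test needs.

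Lower spermatid genes in RS libraries labelled cKO were weighed with tests chosen after the result was seen. Spermatocytes in the spermatid gate are argued against as the whole cause if their RNA is that of the sorted PD libraries. The fall of the 75 stage-up genes needs a share of 87.6% spermatocyte RNA in replicate 1 labelled cKO (quartiles 62.8 and 101). In replicate 2 it needs 52.6% (36 and 58.7). The 12 mitochondrially encoded genes imply 12.4% (9.78 and 13.2) and -0.227%, and 575 stage-down genes 6% (1.59 and 14.3) and 1.3%. Markers of other cells and stress genes fell from PD to RS too, so these lists cannot exclude spermatocytes poorer in such RNA. For 26 meiotic genes the shares are 34.7% (19.6 and 66.2) in replicate 1, overlapping the stage-up quartiles, and 23.1% (13 and 30.3) in replicate 2. With PD replicate 1 labelled cKO as the source, replicate 1 gives 47.9% (22.2 and 57.4), against 86.9% (68.9 and 92.9) for stage-up genes. For fixed lists in replicate 1, 7 of 12 chromatin compaction and 7 of 16 tail accessory genes lay beyond the het spermatocyte level. A share of such RNA alone cannot bring that. With PD replicate 1 labelled cKO as the source, 3 and 0 genes lay beyond its level. A smaller share stays open, and with that source the whole is not excluded in replicate 1. Scaling by 1 factor per library does not account for the fall, since the stage-up genes lay at -1.46 relative to all genes, which such a factor barely moves. Their median was -1.505 after TMM rescaling and -1.317 before it. TMM also applies 1 factor per library, so distortions that differ between genes were not tested. Fewer late spermatids would lower stage-up genes together, as seen for 65 of 75. Shifts had an interquartile range of 1.39 in replicate 1 and 0.42 in replicate 2. How alike the falls would be depends on how far each RNA is confined to late cells. That was not measured, so the spread of shifts does not decide. Loss of late cells and lower transcripts per cell, which the cKO genotype could bring, cannot be told apart.

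Ewsr1 at the het level in both libraries labelled cKO replicate 2 was weighed with tests chosen after the result was seen. A round spermatid library from a control animal is not borne out by its stage-up genes, which lay at -0.876. The 2 het libraries lay within 0.116 of their mean. These genes were chosen on those het libraries, so a further control would lie lower too, and shared het libraries alone gave -0.215. The chromatin compaction list, fixed beforehand, lay at -0.728, where the het libraries lay within 0.171. Only 2 het libraries set either range. Over 14411 genes, the RS differences from het of libraries numbered 1 and 2, which share no library, correlated at r = 0.639. With the het libraries swapped r was 0.667, and the difference within cKO against that within het gave -0.008. A control would bring such a correlation only if it differed from het as replicate 1 did. These values argue against a control for the RS library but do not exclude it. For the spermatocyte library the stage-down shift was -0.068, near het, but its pair's differences correlated with those of the pair numbered 1 at r = 0.274, so a control animal and a knockout with little change cannot be told apart. Scaling by 1 factor per library is excluded, since the replicates labelled cKO differed in Ewsr1 by 0.87 (PD) and 1.2 (RS) on the log2 scale after TMM rescaling. A loxP allele left unrecombined in part of the cells would give smaller shifts in the same direction. For the stage-up genes in RS, the shift of replicate 2 was 46.8% of that in replicate 1. Fixed lists in RS went both ways. Chromatin compaction lay at -1.858 and -0.728 in replicates 1 and 2, but mitochondrially encoded genes lay at 1.138 and -0.14. Yet Ewsr1 was 56.9% below the het mean in RS replicate 1 labelled cKO and not lowered in replicate 2 (-0.336% below). In PD the stage-down shift was -0.068 against 0.557 and the mitochondrial -0.267 against 1.277, with het libraries at up to 0.169 and 0.232. Variation between animals would give such values too, so an unrecombined allele and such variation cannot be told apart.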

How the results depend on the processing

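Of 32 list calls made in the 3 list comparisons, those in RS of chromatin compaction, acrosome, tail, manchette, energy, sex body, ribosomal and stage-up lists kept direction and side of the threshold in all 20 alternatives of camera at its preset correlation; each was lost with an estimated one (adjusted p = 0.922 with an estimated correlation). Chromatin compaction, meiotic division and stage-up lists did so in all 19 for the interaction, and were lost there as well (0.926, 0.926 and 0.885). With fry, none of these lists passed in RS (adjusted p 0.214 to 0.759) or for the interaction (0.498 to 0.777). Of 298 gene results, 125 called, TMM rescaling ended 1 call, gained 1 and turned the sign of 25, and normalized counts ended 18, gained 3 and turned 21, 1 of them (E2f3) past the test both ways. Of 84 list results TMM rescaling ended 5 calls and gained 3, and normalized counts ended 5 and gained 8. Limma without the trend and the highest row per symbol moved no count of calls by over 1.5 times. Depth limits genes with few reads: 3 of 8 called genes in PD and 5 of 6 in RS had under 10 estimated reads. Where an arm kept 1 library, that library was assumed to vary like the other groups. For the changes below the cause was not tested.

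Counts of calls moved as follows. A pseudocount of 0.1 gave 5 lower genes in PD. No filter gave 7 lower in PD, 10 higher and 7 lower in RS, 1199 rises for stage in cKO, and 12 higher and 7 lower for the interaction. TMM rescaling gave 2408 rises for stage in het. Fits of only the 4 libraries compared gave 0 higher and 0 lower in RS (3864 at an unadjusted p under 0.05), 3049 rises for stage in het, and 148 rises and 1665 falls for stage in cKO; the interaction has no such fit. Normalized counts gave 2 higher and 1 lower in PD, 0 and 0 in RS (4518 unadjusted), 2835 rises in het, 4098 rises in cKO and 1 higher for the interaction. With a filter of 10 normalized counts, FPKM gave 1 lower in PD and 1 higher and 1 lower in RS. Normalized counts with that filter gave 2 and 1 in PD, 0 and 0 in RS (5358 unadjusted), 2922 rises in het, 4296 rises in cKO, and 0 higher and 1 lower for the interaction. Without both libraries labelled cKO replicate 2 there were 560 higher and 2623 lower genes and 17 lists in PD, 3091 and 1636 in RS, 3047 rises in het, 5328 rises in cKO, and 7 and 6 for the interaction. Without both replicates 1 there were 17 and 4 genes and 4 lists in PD, 8 and 5 in RS, 3048 rises in het, 721 rises and 2004 falls in cKO, and 1 higher for the interaction. Leaving out 1 library gave ranges of 4 to 8 higher and 1 to 10 lower genes and 3 to 18 lists in PD; 2 to 1271, 1 to 490 and 10 to 13 lists in RS; 175 to 2141 rises and 1413 to 4740 falls in het; 390 to 4751 and 2011 to 3647 in cKO; and 0 to 8, 0 to 8 and 8 to 16 lists for the interaction.

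With the replicate number as a block there were 6 higher and 2 lower genes in PD, 5 and 2 in RS, 1327 rises and 4041 falls for stage in het, 1549 and 3282 in cKO, and 2 and 3 for the interaction. The block turned the direction of spermatogonial markers in RS (adjusted p = 0.995, limma camera) and ended the calls of the spliceosome in RS (0.0591), ribosomal proteins for the interaction (0.0653) and Gm14255 for the interaction (0.0849). In all it ended 3 of 125 gene calls and gained 2, and it ended 2 of 32 list calls and gained 5. Deviations of same-numbered libraries correlated at 0.015, 0.046, 0.001, -0.046 and -0.039 between pairs of groups, and at 0.244 between the 2 groups labelled cKO. The labels give no tie beyond the number and not every pair of groups correlated, so no pairing was used; whether same-numbered libraries labelled cKO, which also share the Ewsr1 level, come from 1 animal is open.

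Results that changed direction follow, with camera's adjusted p for lists; the cause was not tested. In RS, spermatogonial markers did so with a pseudocount of 0.1 (0.893), TMM (0.611), normalized counts (0.29, or 0.309 with the filter of 10) and without both replicates 2 labelled cKO (0.916). Synapsis genes did with TMM (0.812) and normalized counts (0.524 and 0.431), macrophage markers with no filter (0.81), and axoneme genes and histones in the fit of 4 libraries (0.856 and 0.971). Acrbp in RS was -0.1 with TMM and -0.05 with normalized counts. Ewsr1 for stage in het was 0.04 with TMM and 0.12 with normalized counts, and for stage in cKO E2f3 was -2.67 (adjusted p = 0.0113) and Mov10l1 -1.16 with normalized counts. Without both replicates 1, Ewsr1 was 0.01 in PD and 0.01 in RS, and in PD Tnp1 was 0.13, Spink2 0.21, Ldhc 0.16, mt-Co2 -0.38, mt-Co1 -0.2, Clu -0.02 and Vim -0.13. That choice also turned, in PD, chromatin compaction (0.807), acrosome (0.899), tail (0.807), mitochondrially encoded (0.0125) and stage-down genes (0.148), and in RS the axoneme (0.393), mitochondrially encoded (0.187), histone (0.266), macrophage (0.671) and X-linked lists (0.248).

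Ranges over left-out libraries for results that changed direction are log2 fold changes for genes and limma camera's adjusted p for lists. In PD, the log2 fold changes were Ewsr1 -1 to 0.01, Tnp1 -1.71 to 0.13, Spink2 -1 to 0.21, Ldhc -0.85 to 0.16, mt-Co2 -0.38 to 0.9, mt-Co1 -0.2 to 1.24, Clu -0.02 to 1.03 and Vim -0.27 to 0.56. Camera's adjusted p in PD was 0.361 to 0.781 for chromatin compaction, 4.91e-06 to 0.901 for acrosome, 0.00111 to 0.957 for tail, 8.74e-05 to 0.524 for mitochondrially encoded and 2.46e-16 to 0.156 for stage-down genes. In RS, the log2 fold changes were Ewsr1 -1.21 to 0.01, Spink2 -0.06 to 0.03 and Acrbp 0.04 to 0.17. Camera's adjusted p in RS was 0.728 to 0.937 for axoneme, 0.715 to 0.975 for synapsis, 0.594 to 0.965 for stress, 0.0194 to 0.451 for mitochondrially encoded, 0.219 to 0.844 for histone, 0.686 to 0.974 for macrophage, 0.686 to 0.98 for spermatogonial and 0.021 to 0.792 for X-linked genes. For stage the log2 fold changes were Ewsr1 -0.19 to -0.08 in het and -0.85 to 0.36 in cKO, E2f3 4.13 to 4.99 and Mov10l1 0.03 to 0.33 in cKO, and for the interaction Ewsr1 -0.71 to 0.5.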

Other observations

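Sex-linked genes moved in both directions between spermatocytes and round spermatids of het mice. Of 801 X-linked genes, silenced in the sex body of pachytene cells, 106 rose and 166 fell (121 and 173 adjusted over the list alone); of 111 Y-linked genes 18 rose and 3 fell (16 and 3). Rps4x (-3.61 ± 0.32) and Rpl10 (-2.95 ± 0.27) are X-linked genes that fell, and Cypt1 (1.71 ± 0.17) and Cylc1 (1.26 ± 0.16) X-linked genes that rose. Over all 18440 genes 1200 rose and 4143 fell, and markers of other cell types fell in the same comparison (9 of 12 Sertoli, 7 of 8 Leydig, 5 of 5 peritubular and stromal, 10 of 14 spermatogonial).

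Genotype differences were compared between replicate pairs that share no library, over 14411 genes with at least 100 mean normalized counts. In RS the difference of libraries numbered 1 correlated with that of libraries numbered 2 at r = 0.639 (0.667 with the het libraries swapped), where the difference within cKO against that within het gave -0.008. In PD the values were 0.274, 0.218 and 0.026. The slope of replicate 2 on replicate 1 was 0.337 in RS and 0.142 in PD. PD and RS effects correlated at r = 0.455; they share no library, but same-numbered libraries labelled cKO deviated together (0.244), and whether they come from the same animals is not given in the labels.

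A hypothesis written before its test was that long mRNAs lie higher in spermatocyte libraries labelled cKO because of a trend with transcript length. The Spearman correlation with length over 14202 genes was 0.172 in the PD pair numbered 1 but 0.01 in the pair numbered 2, so no trend shared by both PD pairs was found. In RS the pairs gave 0.089 and 0.069 (0.135 and 0.133 with normalized counts). In PD, 658 genes were lower in both libraries labelled cKO than in both het libraries, with a fall of at least 0.5 in the group mean. Their median longest transcript was 2143 bases, against 3138 for the 795 genes higher by the same rule and 3091 for all 14202. The 0.5 holds for the mean of the 2 libraries and not for each.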
